A study of Mus musculus with 12 samples.

How the data were processed

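RNA sequencing counts of 12 mouse brain libraries were analysed. Per the labels, they came from 8 mice that carried loxP-flanked Bmal1 (Arntl) alleles. The mice were positive (KO) or negative (WT) for a tamoxifen-inducible Cre recombinase under the Aldh1l1 promoter, which is active in astrocytes. All received tamoxifen by gavage, 2 mg per day for 5 days at 2 months of age, and brains were taken at 20 months. Per the labels' protocols, the brains were dissociated with collagenase, debris was removed, astrocytes were bound to magnetic beads through the surface antigen ACSA-2, and the unbound cells were kept as flowthrough. RNA was extracted with Trizol and columns and amplified with a SMARTer kit. Astrocyte libraries came from 4 mice of each label, and flowthrough libraries from 2 of the mice of each label. Libraries are named by label, fraction and mouse number.

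Per the file headers, each library has 1 deposited file with the gene identifier, exon coordinates, summed exon length, and a raw read count, CPM and RPKM for each of 41388 genes. The deposited counts are whole numbers. The deposited CPM values equal the count per total count of the library, within 5.1e-11. The deposited RPKM values are those CPM values per kilobase of summed exon length, with no further factor. Per the submitters' processing notes, bcl2fastq, STAR 2.5.1a, Subread, featureCounts 1.4.6-p5 and the GRCm38 build were used. The roles of these tools, the strand setting, the treatment of reads that map to several genes and the annotation release are not given in the sources used here, so values of near-identical paralogs and of overlapping or antisense genes are uncertain. Only the counts were tested. Of the gene identifiers, 40254 matched a gene symbol in the reference name table. The CPM and RPKM columns served only for the checks above. Coordinates are those of the deposited files.

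Genes were tested with edgeR 4.0.16 in R 4.3.3 with the quasi-likelihood test (glmQLFit and glmQLFTest, two-sided), TMM factors, the filterByExpr filter by group, and Benjamini-Hochberg adjustment. An adjusted p under 0.05 was called. The comparison of KO with WT astrocyte libraries used the 8 astrocyte libraries (18527 genes, 6 residual degrees of freedom). The comparison of KO with WT flowthrough libraries, the interaction of label and fraction, and the comparison of the fractions used all 12 libraries with 4 group means (20997 genes, 8 residual degrees of freedom), so that the spread was pooled over the groups. CPM values in the text are TMM-scaled and belong to the fit of their comparison; they are given as mean ± SD, and log2 fold changes as estimate ± standard error. Direction is KO minus WT, or astrocytes minus flowthrough.

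A set of 36 gene lists (cell type markers, clock genes, reactive astrocyte genes and pathways; 610 of 611 listed genes matched) was tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. A list needed 3 tested genes. Each list was also tested with a correlation estimated from the data and with the rotation test fry. Several lists share genes: the glutamate and GABA list holds 4 astrocyte markers, Glul, Slc1a2, Slc1a3 and Slc6a11, for example. The mean log2 CPM of each list was compared between the 8 astrocyte libraries by an exact permutation test.

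The named genes follow a rule. They are Arntl and the clock genes; for each comparison the 8 genes with the largest change in each direction among symbols that are not clone names, with adjusted p under 0.05, mean log2 CPM of at least 3 and no overlap between the groups (with fewer than 5, the 5 with the smallest p, given as values that did not pass); up to 4 members of each list with the smallest p; Bag3, Chil1 (the mouse gene listed as Chi3l1), Gfap, Megf10, Mertk, Hspb8, Sqstm1 and Apoe; and Xist and Y-linked genes as a check of sex. The groups, designs, lists, this rule and the alternatives were fixed before the data were examined, except alternatives named as chosen afterwards.

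The alternatives were RLE or library size scaling, leaving out the 20 most abundant genes, no filter or a CPM of at least 1, DESeq2 1.42.0, limma-voom with or without quality weights, other thresholds, a covariate for non-astrocyte RNA (the mean of the microglia, oligodendrocyte, endothelial and neuron list means), other sets of libraries, the mouse as a block or random effect, and each library left out in turn. The mouse number pairs an astrocyte with a flowthrough library of the same animal in 4 mice. The correlations of their deviations from the group means were -0.0066 for mouse 132, 0.155 for mouse 56, 0.352 for mouse 60 and 0.251 for mouse 64. The main comparisons were fitted without the block.

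Total counts ranged from 38.7 to 51.6 M (M, a factor of 1e+06) per library. A count of 3, taken as the floor, corresponds to 0.0582 to 0.0775 CPM. No molecular identifiers are named in the sources used here, so floors cover counting error only. Each pair of replicates was compared over genes with at least 20 counts: the 14 pairs differed by 26.4 to 271 chi-square units per degree of freedom, far above counting error, so no 2 replicates were the same library.

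The gene test was tested on simulated counts made from the means, dispersions and library sizes of the data, with 100 genes changed 2-fold and 100 changed 4-fold. For KO against WT astrocytes it recovered 31 and 92 of them, with 10 false calls among 133. For KO against WT flowthrough it recovered 10 and 74 (3 false among 87), for the interaction 1 and 37 (1 false among 39), and for the fractions 54 and 87 (10 false among 151). With no gene changed, run for KO against WT astrocytes alone, it made 0 calls. Camera gave p under 0.05 for 4 of 200 random lists. The simulated genes were drawn independently of each other, so neither check covers genes that vary together, as markers of 1 cell type do.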

Results

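The series measured gene expression in astrocytes, and in the cells left after astrocyte capture, from aged mice labelled as astrocyte-specific Bmal1 knockouts (KO) or Cre-negative controls (WT). BMAL1, encoded by Arntl, is the transcription factor that with CLOCK activates the genes of the circadian clock through E-box sites. The 12 libraries fell into 4 groups: KO astrocytes and WT astrocytes (n = 4 mice each) and KO flowthrough and WT flowthrough (n = 2 mice each). Total counts were 44.7 to 49.4 M in KO astrocytes, 38.7 to 50.1 M in WT astrocytes, 51.2 to 51.6 M in KO flowthrough and 45.3 to 51.2 M in WT flowthrough. Mitochondrial genes took 12.6% to 16.98% of counts in KO astrocytes, 13.7% to 21.4% in WT astrocytes, 7.95% to 12.7% in KO flowthrough and 4.66% to 8.20% in WT flowthrough. The first principal component held 61.5% of the variance of the 12 libraries. Among the 8 astrocyte libraries it held 44.2%. It followed the mean of the microglia, oligodendrocyte, endothelial and neuron marker lists (Pearson r = 0.918, exact permutation p = 0.00164; Spearman rho = 0.905, exact permutation p = 0.00456). Without KO 73 and WT 78, the libraries at its ends, r was 0.719. That mean was 6.09 ± 0.34 log2 CPM in KO and 5.79 ± 0.22 in WT astrocytes (SD, n = 4 each; exact permutation p = 0.2). Of its lists, the neuron list ran the other way. On the scale of the 12-library fit it was 5.66 in KO 73 and 6.63 in WT 78, against 7.23 and 5.12 for microglia. The covariate for non-astrocyte RNA used the same mean, so it does not follow each of these cell types. Xist was detected at 2411 counts in KO 73 and 1133 in WT 78, where the Y-linked gene Ddx3y had 3 and 1 counts. The other 6 astrocyte libraries had 2176 to 3092 Ddx3y counts. Each astrocyte group held 1 female-type and 3 male-type libraries. The flowthrough libraries were all male-type (3686 to 4970 Ddx3y counts), so sex was not balanced between the fractions. Astrocyte refits without both KO 73 and WT 78 hold male-type libraries only.

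Arntl (ENSMUSG00000055116, chromosome 7, 113207465 to 113314122) was not lower in the libraries labelled KO. Raw counts were 628, 401, 428 and 645 in KO astrocytes 132, 60, 62 and 73, and 360, 239, 242 and 374 in WT astrocytes 56, 57, 64 and 78. In flowthrough they were 284 and 261 in KO 132 and 60, and 292 and 217 in WT 56 and 64. In astrocytes this was 10.9 ± 1.7 against 6.90 ± 1.3 CPM (SD, n = 4 each), a log2 fold change of 0.66 ± 0.19 that did not pass the edgeR test (adjusted p = 0.473). In flowthrough it was 5.04 ± 0.10 against 4.79 ± 0.70 CPM (n = 2 each), a log2 fold change of 0.08 ± 0.26 (adjusted p = 1). The count sums all exons of the gene, 20 exon intervals, and the floxed exons are not named in the sources used here. Whether the count sees the deletion is therefore not known. Since the count runs against the label, the groups are called by their labels throughout: every KO or WT below means libraries labelled KO or WT.

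The comparison of KO with WT astrocytes asks how captured astrocytes of aged mice differ between the labels. Spon2, a secreted matrix protein, rose from 0.809 ± 0.64 to 111 ± 24 CPM (log2 fold change 7.07 ± 0.55, adjusted p = 0.00103; n = 4 each throughout this comparison). Cxcl5, a chemokine that attracts neutrophils, rose from 1.66 ± 0.37 to 36.8 ± 3.0 CPM (4.47 ± 0.19, adjusted p = 1.4e-05). Fabp7, the brain fatty acid binding protein, rose from 456 ± 160 to 2347 ± 580 CPM (2.36 ± 0.30, adjusted p = 0.0150). Chil1, the mouse counterpart of the secreted glial protein CHI3L1, fell from 122 ± 14 to 42.6 ± 7.0 CPM (-1.52 ± 0.15, adjusted p = 0.00419). Hsd11b1, which regenerates active glucocorticoid, fell from 92.8 ± 2.4 to 28.5 ± 8.1 CPM (-1.71 ± 0.20, adjusted p = 0.0122). In all, 43 of 18527 genes passed, 27 higher and 16 lower in KO. Of the 43, 39 changed at least 2-fold. The 2 groups did not overlap in 4.06% of all tested genes, against 2.86% by chance. They were apart in all of the 43, which the test itself selects for separation. At an unadjusted p under 0.05 there were 994 genes, against 926 by chance. With library size scaling alone 30 genes passed and the share of higher genes moved from 62.8% to 73.3%.

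The other genes with the largest increases by the naming rule, which needs a mean log2 CPM of at least 3, included Hebp2, a heme-binding protein (log2 fold change 3.56 ± 0.25). The rest were the interferon-induced genes Oas2 (2.70 ± 0.20) and Cmpk2 (1.63 ± 0.21), Egfl6 (1.77 ± 0.19) and the phosphate transporter gene Slc20a2 (1.66 ± 0.15). Outside the rule, Slc5a8 (3.29) and Krt28 (3.14), among others, passed with larger increases than Oas2. The largest decrease was in Rpe65, known as the retinoid isomerase of the visual cycle, from 16.2 ± 5.0 to 1.69 ± 0.60 CPM (-3.25 ± 0.34, adjusted p = 0.00598). Ppp1r3g, which targets a phosphatase to glycogen (-1.61 ± 0.21), Steap3, a metalloreductase (-1.52 ± 0.24), Lrtm2 (-1.52 ± 0.23), Cyp4f15, a cytochrome P450 (-1.49 ± 0.18), and Nat8, an acetyltransferase (-1.28 ± 0.19), also fell. Spon2 lies on chromosome 5 at 33213518 to 33218238, Cxcl5 on chromosome 5 at 90759299 to 90761625, Fabp7 on chromosome 10 at 57784881 to 57788450 and Chil1 on chromosome 1 at 134182176 to 134190181. The number of genes passing dropped to 12 without KO 132, 16 without WT 57, 17 without KO 60, 20 without WT 64 or without WT 78, 21 without KO 62 and 22 without WT 56. Spon2, Cxcl5, Hebp2, Oas2, Egfl6, Slc20a2, Rpe65 and Chil1 passed in all 8 refits that left out 1 library. Hsd11b1 missed without WT 57 or KO 60 (adjusted p up to 0.0561), and Cyp4f15 without KO 132 or KO 60 (up to 0.0764). Fabp7 missed without KO 132, KO 60, KO 62, WT 57 or WT 64 (up to 0.0665), and Ppp1r3g without KO 132, KO 62, WT 57, WT 64 or WT 78 (up to 0.0933). Cmpk2 passed only without KO 60 or KO 73 (otherwise up to 0.0834), Lrtm2 only without KO 73 (up to 0.216), Nat8 only without WT 64 (up to 0.188) and Steap3 in none of the 8 refits (up to 0.231).

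**Figure D1:**
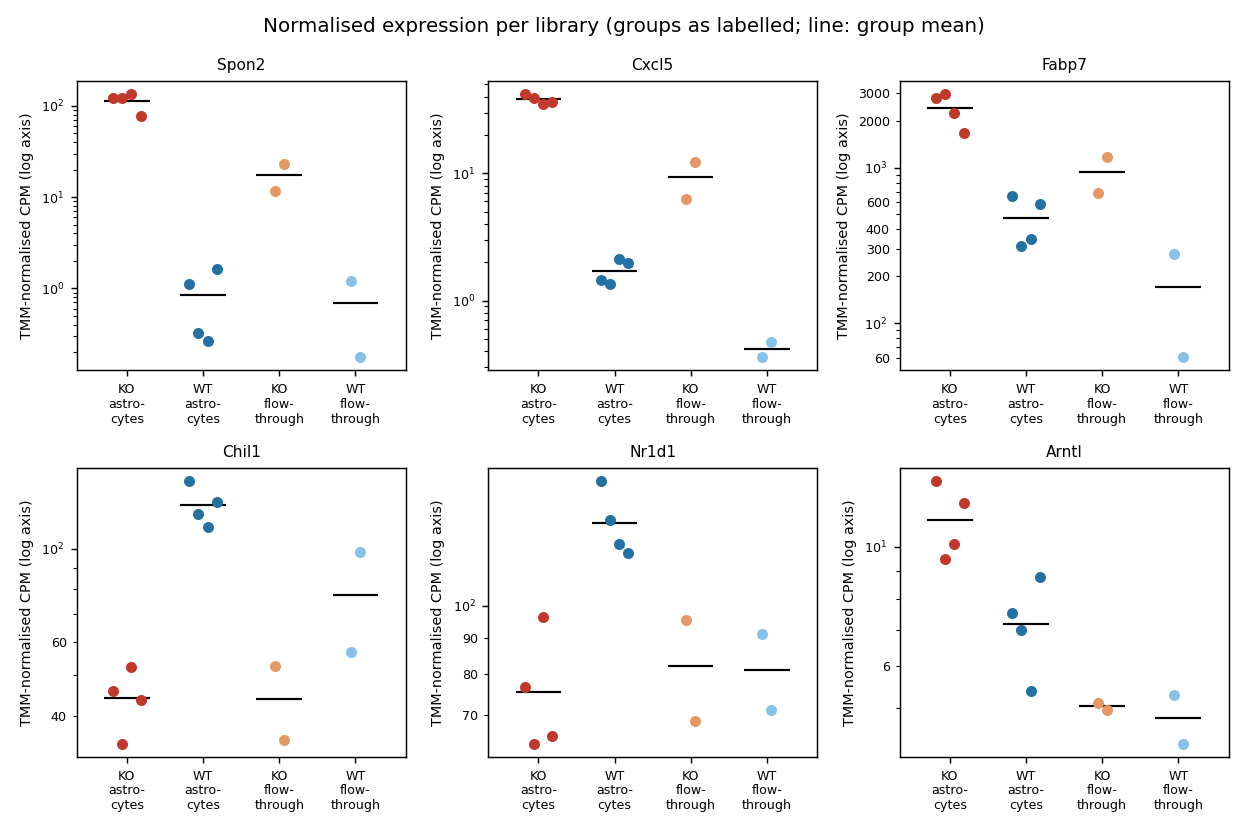
TMM-scaled CPM on a log axis of Spon2, Cxcl5, Fabp7, Chil1, Nr1d1 and Arntl in the 12 libraries, each point 1 library and each line the mean of a group as labelled (KO and WT astrocytes, n = 4 each; KO and WT flowthrough, n = 2 each). Cxcl5 lay at 35.2 to 42.0 CPM in KO astrocytes against 1.35 to 2.11 in WT astrocytes, and at 6.33 and 12.3 in KO flowthrough against 0.362 and 0.475 in WT flowthrough.

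The 2 clock gene lists differed in opposite directions in KO astrocytes by camera with the preset correlation. The list of clock genes activated by BMAL1 through E-boxes was lower, with 14 of 15 members below WT and a median log2 fold change of -0.40 (camera adjusted p = 4.1e-09; adjusted p = 0.313 with an estimated correlation). No member passed over all genes and 6 passed when adjusted over the list alone. They were Nr1d2 (-0.81 ± 0.15, adjusted p over all genes 0.0868), Nr1d1 (-0.79 ± 0.15, 73.0 ± 14 against 126 ± 14 CPM, 0.110), Per2 (-1.01 ± 0.20, 0.123), Per3 (-1.21 ± 0.32, 0.355), Dbp (-0.59 ± 0.18) and Bhlhe40 (-0.40 ± 0.14). Nr1d1 and Nr1d2 encode the repressors REV-ERB alpha and beta, and Per2 and Per3 encode repressors of BMAL1 and CLOCK. Members not passing either way included Cry2 (-0.13 ± 0.17) and Ciart (-0.45 ± 0.36). The list of clock genes repressed by REV-ERB was higher, with 6 of 7 members above WT and a median of 0.47 (camera adjusted p = 0.00137; adjusted p = 0.313 with an estimated correlation). Adjusted over the list alone 4 members passed, Npas2 (1.06 ± 0.26), Arntl, Cry1 (0.54 ± 0.20) and Clock (0.47 ± 0.18), and over all genes 0 (edgeR). DESeq2 called 5 of these genes, Nr1d2 (adjusted p = 2.8e-04), Nr1d1 (0.00211), Per2 (0.00129), Per3 (0.0303) and Npas2 (0.0173). Over the 19 alternatives of each, DESeq2 among them, few passed, with the range of the adjusted p in brackets. Nr1d2 passed in 3 (2.8e-04 to 0.371), Nr1d1 in 2 (0.00211 to 0.404) and Per2 in 1 (0.00129 to 0.317). Per3 passed in 2 (0.00675 to 0.842) and Npas2 in 4 (0.00512 to 0.719). Dbp (0.132 to 0.926) and Arntl passed in none of the alternatives, and Arntl had a log2 fold change of 0.54 to 0.79 in them. The mean log2 CPM of the E-box list was 4.79 ± 0.12 in KO and 5.30 ± 0.20 in WT, and that of the REV-ERB list 4.38 ± 0.07 and 3.97 ± 0.18. The groups did not overlap for either list (exact permutation p = 0.0286, the smallest that 4 against 4 libraries allow). Adjusted over the 36 lists it was 0.514. Only 2 lists reached the smallest p, and with so few the adjusted p cannot fall under 0.05, so it cannot decide. The time of day at which the brains were taken was not used here, so its part in the clock lists was not tested. The microglia, oligodendrocyte, endothelial and lymphocyte marker lists were higher in the same KO libraries and the astrocyte list lower, with the values given next.

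Microglia, oligodendrocyte, endothelial and lymphocyte markers were higher as lists in KO astrocytes, and no member of these lists passed over all genes. All 20 microglia markers and all 20 oligodendrocyte markers were above WT, with median log2 fold changes of 0.54 (camera adjusted p = 0.00602) and 0.76 (1.2e-08), as were 12 of 18 endothelial (0.20, adjusted p = 0.0227) and 8 of 10 lymphocyte markers (0.88, 0.0151). With an estimated correlation the adjusted p was 0.980, 0.873, 0.980 and 0.873. Astrocyte markers were lower, with 26 of 32 below WT and a median of -0.24 (camera adjusted p = 1.1e-05; adjusted p = 0.873 with an estimated correlation). Among the members, Cnp, a myelin enzyme, had a log2 fold change of 1.05 ± 0.20 (adjusted p = 0.109) and passed when adjusted over the list alone. KO 73 carried much of this: without it the microglia median was -0.08 (adjusted p = 0.862) and the astrocyte median -0.13 (0.142), while the oligodendrocyte median was 0.29 (4.4e-05). Without KO 73 the lymphocyte (adjusted p = 0.275), endothelial (0.476), glutamate (0.112), mitochondrially encoded (0.251) and cholesterol lists (0.251) also missed, and 5 lists passed in place of 10; 16 passed without WT 64. The microglia list missed without WT 78 (0.162) and the lymphocyte list without WT 57 (0.0579). The endothelial list missed without KO 132 (0.0808), WT 56 (0.127), WT 57 (0.274) or WT 78 (0.386). Without both KO 73 and WT 78, a choice made after seeing the data, 36 genes passed, 29 of them among the 43.

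The glutamate and GABA handling, cholesterol synthesis and mitochondrially encoded lists were lower in KO, beside these shifts in cell type markers. The glutamate list had 15 of 17 members below WT and a median of -0.29 (camera adjusted p = 5.4e-04; adjusted p = 0.873 with an estimated correlation). Gabrg1, a GABA receptor subunit (-0.79 ± 0.15), passed when adjusted over the list alone, and Glul, glutamine synthetase, had -0.54 ± 0.18. The cholesterol synthesis list (17 of 20 below WT, median -0.14, camera adjusted p = 0.0151) and the mitochondrially encoded genes (13 of 13 below WT, -0.32, 0.00602) had adjusted p = 0.980 each with an estimated correlation. The direction of the mitochondrially encoded list turned with the covariate for non-astrocyte RNA (median 0.038, adjusted p = 0.715), and without KO 73 and WT 78 the median was -0.036 (adjusted p = 0.893). The cholesterol list missed without WT 56 (adjusted p = 0.127) or KO 60 (0.0676), and the mitochondrially encoded list without WT 57 (0.168) or WT 78 (0.208). Of all list members only Fabp7 passed over all genes. It belongs to the lipid transport list (median 0.11, adjusted p = 0.380), where Fabp7 and Lrp4 (0.42 ± 0.12) were higher and Lcat (-0.69 ± 0.20) lower when adjusted over the list alone. In the synapse-shaping list (0.03, 0.377) Bcan (-0.82 ± 0.14), Chrdl1 (-0.93 ± 0.26) and Gpc5 (-0.58 ± 0.17), all secreted or cell-surface proteins, were lower on that adjustment. In the phagocytosis list (0.01, 0.939) Mfge8, a bridge between dying cells and phagocytes (-1.04 ± 0.22), and the receptor gene Mertk (-0.60 ± 0.16) were lower in the same way.

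The remaining lists did not pass in KO astrocytes. The chaperone list around BAG3, a co-chaperone of selective autophagy, had a median of 0.11 (adjusted p = 0.223) and the autophagy list 0.02 (0.459). Bag3 itself had 23.1 ± 1.8 against 15.7 ± 2.4 CPM, a log2 fold change of 0.56 ± 0.14 (adjusted p = 0.348), and its partner Hspb8 had -0.05 ± 0.13 and Sqstm1 -0.03 ± 0.10. Gfap, the intermediate filament raised in reactive astrocytes, had 2027 ± 959 against 991 ± 312 CPM (1.03 ± 0.36, adjusted p = 0.683; 1.58 and 3.8e-04 with the covariate for non-astrocyte RNA, range of adjusted p 3.8e-04 to 0.999 over 19 alternatives). The pan-reactive, A1 and A2 reactive lists had medians of 0.09, 0.04 and 0.39 (adjusted p = 0.380, 0.848 and 0.223). In the A1 list Amigo2 (-1.202 ± 0.25) was lower when adjusted over the list alone. Apoe had -0.15 ± 0.32 and Megf10 0.32 ± 0.16. Medians of the other pathway lists were 0.11 for lysosome genes (adjusted p = 0.181), 0.07 for interferon response (0.943) and 0.02 for immediate early genes (0.563). They were -0.01 for redox genes (0.974), 0.11 for ER stress (0.943), -0.03 for nuclear oxidative phosphorylation (0.459) and -0.09 for ribosomal proteins (0.124). Those of the other cell type lists were 0.54 for disease-associated microglia (0.268), 0.80 for border macrophages (0.0638), 0.40 for choroid plexus (0.0815). They were 0.16 for ependymal cells (0.563), 0.06 for pericytes (0.440), 0.23 for fibroblasts (0.249), and 0.18 for blood (0.943), -0.09 for neurons (0.402), 0.19 for oligodendrocyte precursors (0.756), 0.30 for neural stem cells and neuroblasts (0.221) and -0.06 for sex-linked genes (0.943). Adjusted over the list alone, Vcan (-0.98 ± 0.24) was lower in the precursor list. Median, mean and camera differed in sign for the precursor, blood, pan-reactive, A1, phagocytosis, immediate early, interferon, synapse-shaping and sex-linked lists.

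**Figure D2:**
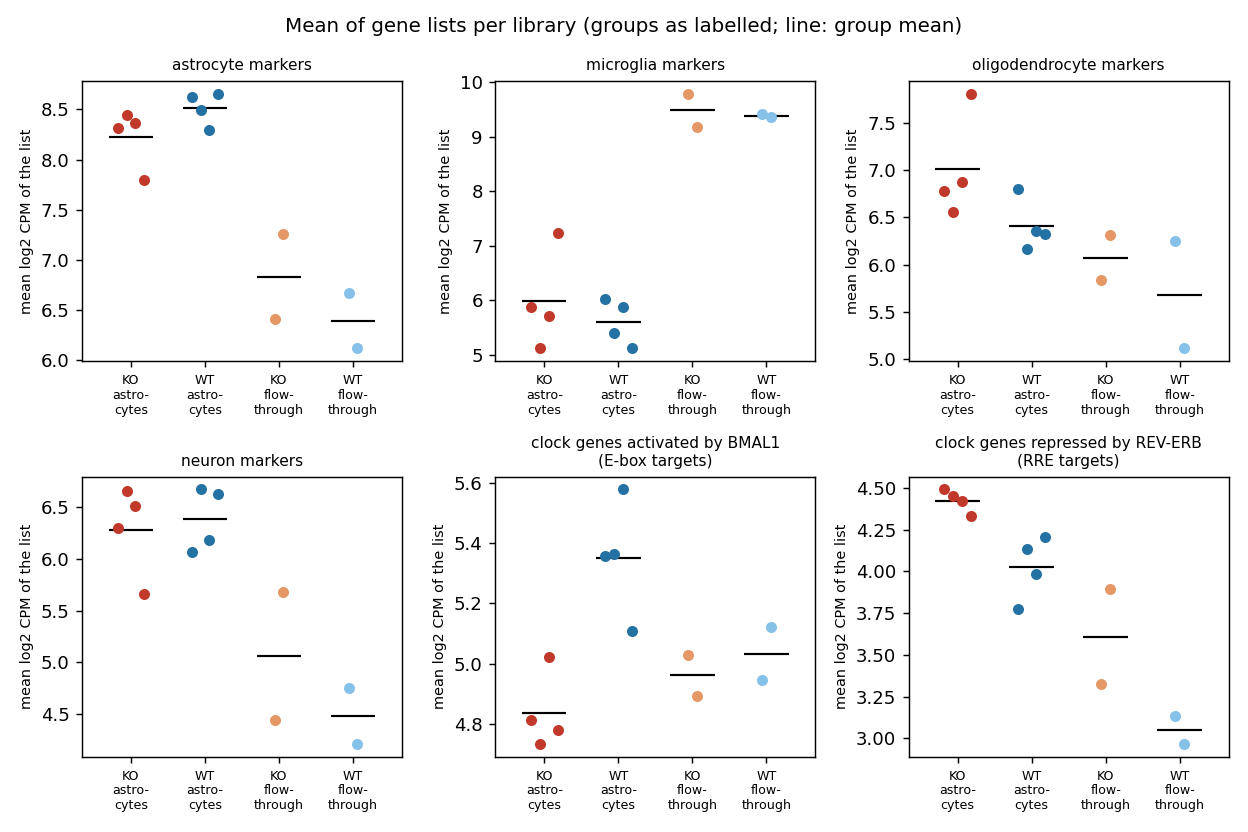
Mean log2 CPM of 6 gene lists in the 12 libraries, each point 1 library and each line the mean of a group as labelled (KO and WT astrocytes, n = 4 each; KO and WT flowthrough, n = 2 each). In the E-box panel the 4 KO astrocyte libraries lay at 4.73 to 5.02 and the 4 WT astrocyte libraries at 5.11 to 5.58, and in the microglia panel KO 73 lay at 7.23 against 5.12 to 5.87 in the other KO astrocyte libraries.

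The comparison of KO with WT flowthrough asks whether the cells left after astrocyte capture differed as well. Flowthrough still held astrocyte RNA: Aldh1l1 had 54.8 and 81.9 CPM in KO 132 and 60, and 59.4 and 63.6 in WT 56 and 64. Uncaptured astrocytes and other cells were therefore not told apart in this comparison. Cxcl5 was higher in KO flowthrough, at 9.33 ± 4.3 against 0.418 ± 0.08 CPM (SD, n = 2 each; log2 fold change 4.47 ± 0.37, adjusted p = 0.00136). It was the only gene of 20997 to pass in edgeR, and its groups did not overlap, which chance gives for 33.3% of genes. Among the values that did not pass, Egfl6 (2.88 ± 0.47), Hebp2 (2.39 ± 0.42), Slc20a2 (1.39 ± 0.23) and Lrrn3 (1.08 ± 0.19) had the smallest p among genes higher in KO, and Col19a1 (-4.64 ± 0.71), Rpe65 (-2.49 ± 0.55), Sfrp5 (-1.57 ± 0.36), Igfbp2 (-0.75 ± 0.17) and Bdh1 (-0.73 ± 0.19) among genes lower. Of the 43 genes that passed in astrocytes, 39 had the same direction in flowthrough, where 46.9% of all genes did, and 26 had an unadjusted flowthrough p under 0.05, all in the same direction. Their median size was 1.63 in astrocytes and their median in that direction 0.82 in flowthrough. The same 4 mice gave libraries to both comparisons, so these are not independent. At an unadjusted p under 0.05 there were 973 genes, against 1050 by chance. Cxcl5 missed without WT 56 (adjusted p = 0.1003) or WT 64 (0.0589), with limma-voom (0.0897) and with the 4 flowthrough libraries alone (0.557). It reached 9.0e-26 with DESeq2, which called 23 genes. Without KO 132, 5 genes passed in edgeR.

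In flowthrough 16 of the 36 lists passed with the preset correlation and 0 with an estimated one, where all 16 had adjusted p = 0.780 to 0.849. KO flowthrough 60 stood apart and carried most of them: without it 2 of the 16 passed, the endothelial and chaperone lists, and the medians were -0.059 for neuron, 0.0061 for astrocyte, -0.0092 for oligodendrocyte, 0.11 for precursor markers and 0.020 for glutamate genes. Without WT 64 7 passed, with the oligodendrocyte median at -0.27, and without KO 132 or WT 56 the endothelial (adjusted p = 0.285 and 0.685) and ER stress lists (0.0869 and 0.155) missed, and without KO 132 the blood list (0.0691). These refits were chosen after seeing the data. With all libraries, neuron (median 0.80), astrocyte (0.52), endothelial (0.50), oligodendrocyte precursor (0.44) and oligodendrocyte markers (0.20) were higher in KO, together with mitochondrially encoded (0.67), glutamate (0.48), synapse-shaping (0.47) and ribosomal protein genes (0.25). Blood (-1.41), ependymal (-0.91) and choroid plexus markers (-0.65), interferon response (-0.47), chaperone (-0.26) and ER stress genes (-0.22) were lower. The list repressed by REV-ERB was higher (median 0.52, camera adjusted p = 0.00801), but not without KO 60 (0.19, adjusted p = 0.443). In it 1 member, Npas2 (2.24 ± 0.47), passed when adjusted over the list alone, as did Lrp4 and Fabp7 (2.46 ± 0.62) in the lipid transport list. No list member passed over all genes. The E-box list had a median of -0.19 and did not pass (camera adjusted p = 0.414), with Nr1d1 at 0.01 ± 0.24 and Per2 at -0.20 ± 0.34. Chil1 had -0.82 ± 0.28 (edgeR adjusted p = 1). Median, mean and camera differed in sign for the border macrophage, lymphocyte, autophagy, redox, oxidative phosphorylation and sex-linked lists.

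The interaction tests whether the difference between KO and WT itself differed between astrocytes and flowthrough. No gene passed in edgeR (0 of 20997; 828 at an unadjusted p under 0.05, against 1050 by chance). Limma-voom called 0 and DESeq2 called 8, 5 of them with a larger KO minus WT value in astrocytes. Among genes that did not pass, the smallest p were those of Slc5a8 (log2 difference 3.47 ± 0.65), Prokr2 (3.13 ± 0.60), Col19a1 (4.08 ± 0.80), Arhgef3 (1.202 ± 0.25) and Oas2 (1.73 ± 0.37) on the positive side. On the negative side they were those of Mfsd2a, a lipid transporter (-1.55 ± 0.27), Lrrn3 (-1.13 ± 0.23), Plpp4 (-2.02 ± 0.45), Fam19a1 (-1.80 ± 0.40) and Cox4i2 (-1.19 ± 0.28). Arntl had 0.57 ± 0.32 and Nr1d1 -0.81 ± 0.29. Of the lists, 15 passed, 7 positive and 8 negative, and 0 with an estimated correlation (adjusted p = 0.790 for each). Without KO flowthrough 60 and KO astrocytes 73, a choice made after seeing the data, 5 lists passed and 3 of the 15 were among them: the E-box (-0.47), chaperone (0.29) and mitochondrially encoded lists (-0.55). The neuron difference was then 0.14 and the astrocyte difference -0.18 (adjusted p = 0.338 and 0.440). With the mouse as a block 19 lists passed, 5 positive and 14 negative, of which 6 were among the 15. These were the E-box list (median log2 difference -0.41, and -0.47 with the block), the astrocyte list (-0.69 and -0.52), the glutamate list (-0.85 and -0.60), the synapse-shaping list (-0.62 and -0.46), the choroid plexus list (0.99 and 0.59) and the chaperone list (0.40 and 0.27). The precursor, neuron and mitochondrially encoded lists missed with the block. Another 12 lists, each called without the block, with it or both ways, changed the direction of their test. Among them were disease-associated microglia (0.81, and -0.45 with the block), ependymal (1.10 and -0.45) and interferon genes (0.51 and -0.36). Lists called neither way were not counted, though some changed the sign of their median, such as the A2 list (0.49 and -0.39). The pan-reactive, autophagy and redox lists differed in sign between median, mean and camera.

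The comparison of astrocytes with flowthrough shows what the bead capture separated. Astrocyte markers were higher in the captured fraction: 31 of 32 passed as higher and 1, Slco1c1, as lower, with a median log2 fold change of 1.84 (for example Fgfr3 2.25 ± 0.20, Gjb6 1.89 ± 0.17 and Atp1b2 1.98 ± 0.19). Microglia markers were lower, all 20 of 20, with a median of -3.57 (Olfml3 -3.95 ± 0.29, Siglech -3.68 ± 0.30). So were all 10 blood (-5.19), 11 of 12 lymphocyte (-4.96), all 10 choroid plexus (-2.43, for example Kl -2.98 ± 0.33) and 17 of 18 endothelial markers (-1.14). Neuron markers (19 of 20, median 1.58, Snap25 2.01 ± 0.32), precursor markers (7 of 10, 1.15) and oligodendrocyte markers (9 of 20, 0.98, Cnp 1.25 ± 0.24) were higher in the captured fraction. The genes with the largest increases by the naming rule were Cbln3 (3.36 ± 0.43), Gabra6 (3.19 ± 0.47), Cbln1 (2.88 ± 0.40), Gria4 (2.84 ± 0.30), Kcng4 (2.75 ± 0.27), Neurod1 (2.71 ± 0.42), Hrh1 (2.64 ± 0.26) and Rgs8 (2.61 ± 0.27). Genes lower in the captured fraction by the same rule included the immunoglobulin gene Ighg2b (-7.21 ± 0.99, 53.0 ± 33 and 38.7 ± 23 CPM in KO and WT flowthrough, n = 2 each) and Prg2 (-7.50 ± 0.94).

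Other lists that were higher in the captured fraction were glutamate and GABA handling (15 of 17 members, median 1.58, Slc1a3 1.97 ± 0.22), synapse-shaping genes (14 of 17 higher and 1 lower, 1.74), cholesterol synthesis (18 of 20, 1.002), mitochondrially encoded genes (12 of 13, 1.04), nuclear oxidative phosphorylation (15 of 24, 0.47), ribosomal proteins (10 of 36, 0.39; 5 when adjusted over the list alone) and the list repressed by REV-ERB (5 of 7, 0.87, with Arntl 0.87 ± 0.17). Lower were lysosome genes (22 of 34 lower and 2 higher, -1.01, Grn -2.82 ± 0.27), immediate early genes (18 of 20, -1.74, Btg2 -2.52 ± 0.34), disease-associated microglia genes (15 of 18 lower and 1 higher, -2.54), interferon response genes (12 of 19, -1.01), A1 reactive genes (7 of 12 lower and 2 higher, -1.65, with the major histocompatibility gene H2-T23), ER stress genes (10 of 16 lower and 3 higher, -0.86) and border macrophage markers (3 of 8, -1.10). Adjusted over the list alone the counts moved by at most 2 members in every list but the ribosomal one. These 23 lists passed with camera (adjusted p from 2.5e-13 to 0.0409) and 0 with an estimated correlation (adjusted p = 0.366 to 0.637). The neural stem cell and sex-linked lists differed in sign between median, mean and camera. In all, 10333 of 20997 genes passed (5204 higher, 5129 lower), 6062 of them without overlap between the fractions, and 11662 had an unadjusted p under 0.05. Over all tested genes the fractions did not overlap in 29.2%, against 0.404% by chance. Library size scaling alone shifted the median of all genes to -0.14 and the share of higher genes among those passing from 50.4% to 42.8%. At a minimum change of 2-fold 5928 genes passed.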

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

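The tests of the 3 patterns below were chosen only after the result was seen, and the criteria for the chromosome segment and the oligodendrocyte markers were tightened after their values were seen; the tests of other splits of the libraries were chosen before.

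Of 164 groups of 4 libraries tested for a single distant library, 7 had one, where chance gives about 1 in 20 groups, or 8.2. KO 73 lay apart in the A2 reactive list (mean log2 CPM 3.08, others 1.82 to 2.03), the sex-linked list (-3.62, others 4.30 to 4.35) and Slc20a2 (95.6 CPM, others 128 to 132). KO 132 lay apart in Wee1 (1.33 CPM, others 2.46 to 2.69) and Sqstm1 (78.2 CPM, others 86.4 to 87.9). WT 78 lay apart in the sex-linked list (-4.22, others 4.27 to 4.47), and WT 64 in Cry1 (7.20 CPM, others 4.57 to 5.01).

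For 15 gene lists the difference between KO and WT itself differed between the fractions by camera on the interaction, and each lost its call with an estimated correlation (adjusted p = 0.790). The median log2 difference was negative for the E-box list (-0.41, adjusted p = 0.00114), astrocyte markers (-0.69, 2.8e-08), precursor markers (-0.67, 0.00871), neuron markers (-0.74, 0.00131), glutamate and GABA genes (-0.85, 8.0e-05), synapse-shaping genes (-0.62, 0.00674), mitochondrially encoded genes (-1.03, 1.3e-06) and ribosomal protein genes (-0.35, 3.1e-04). It was positive for disease-associated microglia (0.81, 0.0359), ependymal (1.10, 0.00260), choroid plexus (0.99, 1.6e-04) and lymphocyte markers (0.92, 0.0286), and for chaperone (0.40, 1.6e-04), lysosome (0.23, 0.0314) and interferon genes (0.51, 0.0164). With the mouse as a block the disease-associated microglia (-0.45), ependymal (-0.45), lymphocyte (-0.12), lysosome (-0.18), interferon (-0.36) and ribosomal lists (0.080) reversed, and the precursor (-0.50), neuron (-0.19) and mitochondrially encoded lists (-0.37) lost their call. Without KO flowthrough 60 and KO astrocytes 73, a choice made after seeing the data, only the E-box (-0.47), chaperone (0.29) and mitochondrially encoded lists (-0.55) of the 15 passed, and the neuron (0.14), lysosome (-0.17) and interferon lists (-0.13) reversed.

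Microglia and oligodendrocyte markers were higher in KO astrocytes with the preset correlation, but not with an estimated one (camera adjusted p = 0.980 and 0.873). Library KO 73 may carry the microglia part, since the median without it was -0.076. For the oligodendrocyte part this stays open, since without KO 73 the median fell by more than 1.5 times, from 0.76 to 0.29, while the list still passed with the preset correlation (camera adjusted p = 4.4e-05). If a lower share of astrocytes raised all other cell types alike, the oligodendrocyte minus neuron list mean would not differ. It was 0.70 higher in KO (exact permutation p = 0.286). The test cannot decide, because neuron markers were themselves higher in the captured fraction. Among the astrocyte libraries they were lowest in KO 73, as astrocyte markers were (list means 5.66 and 7.795 log2 CPM). A lower share of astrocytes stays open. A larger oligodendrocyte share in KO brains was not tested.

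The Arntl count was not lower in KO astrocytes. The tables argue against a swap of some of the libraries between the groups, because the E-box list means did not overlap (highest KO 4.97, lowest WT 5.05; exact permutation p = 0.0286, the smallest possible). They argue against an exchange of all labels too, as far as the E-box list reports BMAL1 activity. An exchange would put the higher list mean in the mice without BMAL1, and the list was 0.51 lower in KO. The Arntl count runs against the labels, but whether it sees the deletion is not known. A candidate explanation is less REV-ERB repression of Bmal1: the mean of the REV-ERB list without Arntl was 0.36 higher in KO (lowest KO 4.41, highest WT 4.32; exact permutation p = 0.0286). That the count, summed over 20 exon intervals, does not see the deletion stays open, because the position of the deleted part was not used here. The time of day at which the brains were taken was not used either. Whether it differed between the groups was not tested, so the clock lists do not separate it from the label.

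The 9 genes with Nat8 symbols on chromosome 6 (85706727 to 85933379) were all lower in KO astrocytes, 8 with an unadjusted p under 0.05, and 2 passed, Nat8 and Nat8f3; Alms1-ps2, a pseudogene among them, was lower too (10 of 10). A chromosome segment of another origin that came with the Cre could be the cause. Of the 119 other neighbours within 5 Mb 5 had p under 0.05, 4.20% against 5.33% of other genes (Fisher exact p = 0.837; 6 of 120 and p = 1 with Alms1-ps2 as a neighbour), which leaves it open, as a segment need not change many genes. Reads shared between members stay open in part, since the log2 fold changes differed by more than their errors (chi-square heterogeneity test of the edgeR estimates, p = 1.2e-11 over the 10 and 8.0e-10 over the 9). A biological cause was not tested.

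Among the 35 splits of the 8 astrocyte libraries into 4 and 4, only the real one gave as many as 43 genes (highest other 17). That is 1 of 35, the smallest share these splits allow, so it argues against chance for that number but cannot exclude it. For the 10 lists chance cannot be excluded either: 27 of 35 splits gave as many. The highest other gave 26, more than 1.5 times the real number. Whether the samples have a structure of their own or the preset correlation was too small was not separated. Between the fractions, with 2 groups, 1 of 85 splits drawn from 495, the real one, gave as many as 10451 genes (highest other 2817). This argues against chance for that number. For the 23 lists chance stays open (15 of 85, highest other 26). In the 16 splits that part the 4 pairs of libraries from 1 mouse as the real one does, the highest other gave 1 gene and 27 lists; these others mix the fractions within each group.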

How the results depend on the processing

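The alternatives that left out KO 73 with WT 78, or 3 libraries, or KO flowthrough 60 with KO astrocytes 73, the flowthrough lists with 1 library left out and the astrocyte marker covariate were chosen only after the data were seen. Over all alternatives, 1003 of 1256 list values stayed on their side of the threshold, 168 lost their call, 48 gained one and 37 reversed. For named genes the numbers were 13128, 110, 108 and 0 of 13346. A reversal was counted only where the main fit or the alternative called the value. Values called in neither that changed sign are therefore among those that stayed. Unless stated, the cause was not tested.

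With an estimated correlation camera called 0 lists in each of the 4 comparisons, where the preset gave 10, 16, 15 and 23. Directional fry called 0 in astrocytes, 0 in flowthrough and 0 in the interaction, and mixed fry 4, 0 and 0. For the fractions they called 28 and 33. Mixed fry does not ask for a common direction of the members. The 4 lists were the E-box (mixed fry adjusted p = 8.2e-04, directional 0.0980), REV-ERB (8.2e-04 and 0.1265), lipid transport (0.00447 and 0.833) and precursor lists (0.0111 and 0.971).

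For KO against WT astrocytes, DESeq2 called 183 genes (89 higher, 94 lower), voom with quality weights 111, an adjusted p under 0.1 called 75 by construction and the non-astrocyte covariate 176, each with all 43 among them. RLE scaling gave 43, library size 30, no top 20 genes 42, no filter 50, the stricter filter 48, voom 31, a 2-fold minimum 39, 12 libraries 45. Leaving out 1 library gave 12 to 37 genes and 5 to 16 lists. Arntl stayed at 0.54 to 0.77 on leaving out 1 astrocyte library and at -0.07 to 0.23 on leaving out 1 flowthrough library.

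The covariate gave 11 lists, 2 of them among the 10. The microglia, oligodendrocyte, endothelial and neuron lists, which make up the covariate, were not tested with it. The microglia, oligodendrocyte and endothelial lists of the 10 could therefore not be among the 11. It reversed disease-associated microglia (-0.60), ependymal (-1.01), border macrophage (-0.50), mitochondrially encoded (0.038), oxidative phosphorylation (0.15) and ribosomal lists (0.19). Without KO 73 and WT 78 there were 11 lists, 3 shared; reversed were microglia (-0.18), disease-associated microglia (-0.41), neuron (0.12), endothelial (-0.16), ependymal (-1.02), oxidative phosphorylation (0.14) and ribosomal lists (0.16), and the mitochondrially encoded list (-0.036) by the direction of its test alone. On leaving out 1 library, the interferon median ranged from -0.31 (without KO 73) to 0.29 (without KO 60, where its test turned) and the microglia median from -0.076 (without KO 73, reversed) to 0.80 (without KO 60).

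For flowthrough, DESeq2 called 23 genes, voom 0, the 4 flowthrough libraries alone 0 and the astrocyte covariate 1; leaving out 1 library gave 0 to 5, with the lone sample left assumed to vary like the other groups. Leaving out 1 flowthrough library gave 2 (without KO 60) to 15 lists, with medians of 0.0061 to 0.98 for astrocyte, -0.059 to 1.25 for neuron, -0.27 to 1.07 for oligodendrocyte markers and 0.020 to 0.83 for glutamate genes, each with a test that turned at the lower end. Without KO flowthrough 60 and KO astrocytes 73 the interaction gave 5 lists, 3 shared, and microglia (-0.43), neuron (0.14), lysosome (-0.17), interferon (-0.13) and oxidative phosphorylation lists (0.19) reversed. For the interaction DESeq2 called 8 genes and every other alternative 0. For the fractions a 2-fold minimum gave 5928 genes by construction, and the other alternatives 7464 (without KO flowthrough 132) to 12499 (mouse as random effect).

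With the mouse as a block the interaction gave 0 genes and 19 lists, 6 shared, and the fractions 10994 genes and 25 lists. Interaction lists that reversed were microglia (-0.54), disease-associated microglia (-0.45), ependymal (-0.45), border macrophage (-0.87), lymphocyte (-0.12), blood (-1.14), A1 (-0.39), lysosome (-0.18), immediate early (-0.79), interferon (-0.36), oxidative phosphorylation (0.20) and ribosomal (0.080). Endothelial, pericyte, autophagy and cholesterol lists gained a call (-0.79, -0.93, 0.12 and -0.28). The block uses only the 4 mice with both fractions, which leaves out KO 62, KO 73, WT 57 and WT 78 from the difference. Depth limits genes near 0.0582 to 0.0775 CPM, the level of 3 counts.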

Other observations

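Other genes among the 43 of the astrocyte comparison lie outside the naming rule, and those given here were chosen after their values were seen. Plat, tissue plasminogen activator (log2 fold change 1.63 ± 0.26), Mmp14, a membrane-bound matrix protease (1.08 ± 0.15), and Wif1, a secreted WNT inhibitor (3.04 ± 0.42), were higher in KO astrocytes. The counts of Esr1, the estrogen receptor alpha (2.24 ± 0.23), and Cdkn1a, the cell cycle inhibitor p21 (1.37 ± 0.21), were higher too. In flowthrough Esr1 had a log2 fold change of 0.28 (edgeR unadjusted p = 0.541). Whether reads of the tamoxifen-inducible Cre transgene, which only KO mice carry, were counted at Esr1 was not tested. Mfsd2a, a transporter of lysophospholipids (-1.21 ± 0.17), and Sfrp5, another secreted WNT inhibitor (-1.78 ± 0.26), were lower (edgeR adjusted p = 0.0277 and 0.0363; n = 4 each).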
